A study of Schistosoma mansoni with 6 samples.

How the data were processed

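RNA was sequenced from adult male Schistosoma mansoni of the NMRI strain, the blood fluke. Per the labels' protocols, worms were taken from mice 43 days after infection, given 200 Gy of gamma rays or a mock exposure, and cultured for 48 hours. Head and testes were then cut away, and total RNA was extracted with a DNase step from pools of 14 to 18 worms. The 6 libraries, 3 mock-irradiated controls and 3 irradiated, were made with a TruSeq RNA kit, pooled and sequenced on a single lane for 100 cycles, per the labels. The labels name the libraries A, B and C in each group and do not say whether the pools came from separate infections, so p-values measure the spread between these pools.

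The deposited table gives, per gene and library and per the file headers, whole-number counts of total and unique exon reads, of total and unique gene reads (introns included) and of exon-exon reads. It also gives RPKM values, an exon length, and the authors' fold change and P-value for the comparison. The deposited RPKM values matched total exon reads divided by exon length and by the library's total gene reads, with a largest relative difference of 3.77e-08. The deposited P-value matched an equal-variance test of the 3 RPKM values against 3, unadjusted. The aligner, counting program, genome build and annotation release are not given in the sources used here. Of 13305 rows, 2535 had an exon length of 0, among them 2429 tRNA and 69 rRNA rows, and were left out of the main test, which used the 10770 rows with exons. Those without exons held between 0.654% and 1.40% of a library's gene reads. The gene identifiers are given as in the file, and 9647 of the rows with exons matched a locus tag in the RefSeq table of assembly ASM23792v2, which was used only to see which genes neighbour each other. No coordinates are given, because the authors' build is not stated. Product names come from the file. It gives no name for 2103 rows with exons and "hypothetical protein" for 3116.

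Total exon reads ranged from 17577059 to 29641087 per library. A gene with 0 reads could have had up to 3 reads, which is 0.101 to 0.171 CPM (read counts scaled by library size). Such limits cover counting error only. Exon reads were tested because RPKM is built on them. Genes with enough reads were kept with filterByExpr (8885 genes), scaled with TMM factors, and tested with edgeR 4.0.16 quasi-likelihood models in R 4.3.3, irradiated against control, with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. Standard errors are the unshrunken log2 fold change divided by the square root of F. Deposited counts were also fitted with DESeq2 1.42.0, and log2(RPKM + 0.5) with limma 3.58.1. On simulated counts with 200 changed genes among 8885, edgeR recovered 56% of the genes changed by 1.25-fold, 86% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 11 false calls among 179.

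The design, the alternatives, 18 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one, with fry, and by Fisher's exact test of members called lower. P-values were adjusted over the 18 lists. For each list, calls are also given adjusted over the list alone. The pattern for the tegument list also matched digits inside 30 gene identifiers, and those genes were left out of the list, a choice made after seeing the data. The named genes were 4 stem-cell genes fixed by identifier, the largest changes among called genes with a mean log2 CPM of at least 1 and no overlap between groups (10 falls and 8 rises with a product name, 2 of each whatever the name), up to 4 called members of each list or its 2 most abundant members where fewer than 2 were called, and the 2 most abundant called genes in each direction. This gave 66 genes. The 4 fixed genes and the list of germline and stem cell regulators were picked from knowledge of this study's own work, so their direction is not independent evidence. GO terms in the deposited table, with 5 to 500 genes, were tested for enrichment among called genes against the 7580 tested genes that carry a term, a choice made after seeing the data. The kit is not stated to mark strand, so overlapping genes on opposite strands cannot be told apart, and near-identical copies of a gene can share reads.

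Alternatives tried were RLE and upper-quartile scaling, no filter beyond 1 read, at least 5 CPM in 3 libraries, the replicate letter as a block, leaving out each library, a pseudocount of 0.1, and unique exon reads. Gene reads with introns, exon-exon reads and thinning of every library to the smallest were added after seeing the data.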

Results

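To find the genes that depend on cells sensitive to irradiation in adult schistosomes, posterior somatic tissue of male worms was compared 48 hours after 200 Gy of gamma irradiation or a mock exposure. Gamma rays at such doses stop cell division, and in flatworms the dividing somatic cells are stem cells called neoblasts. The 3 control libraries held 26858868, 22825143 and 17577059 exon reads and the 3 irradiated libraries 29641087, 21594259 and 23818660. Exons took 82.9% to 87.2% of gene reads, lowest in control B. The groups parted on the first principal component, which carried 61.3% of the variance of log2 CPM. Every pair of libraries differed by more than sampling noise.

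Among the genes lower after irradiation were 17 of 44 measured DNA replication genes, 8 of 42 mitosis and cell cycle genes and 5 of 9 germline and stem cell regulators, none of whose lists had a member called higher. Of these 5 regulators, 4 were fixed from knowledge of this study's own work. Of 8885 genes tested, 221 were lower and 55 higher after irradiation at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). By at least 2-fold, 100 were lower and 7 higher. The median change was 1.90-fold among genes called lower and 1.31-fold among those called higher. Among the falls, 59 were of at least 4-fold and 27 of at least 10-fold. The 2245 genes whose groups did not overlap made 25.3% of those tested, against 10% by chance, and included all 276 called genes. In the authors' deposited table, 126 genes had a fold change of -2 or lower and 28 of 2 or higher at an unadjusted p under 0.05, and 98 of the 100 genes lower by at least 2-fold here were among the former. Without a fold limit, 729 were lower and 726 higher there at that unadjusted p. The total of called genes depended on single libraries: the count of genes called lower was 359 without control A, 723 without irradiated B, and between 119 and 127 without control B, control C, irradiated A or irradiated C, and that of genes called higher was 125, 129, 18, 16, 22 and 33 in the same order of libraries. The count lower by at least 2-fold lay between 89 and 117 in these fits and that higher by at least 2-fold between 3 and 14, while the requirement of 5 CPM in 3 libraries left 27 of the 100.

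**Figure D1:**
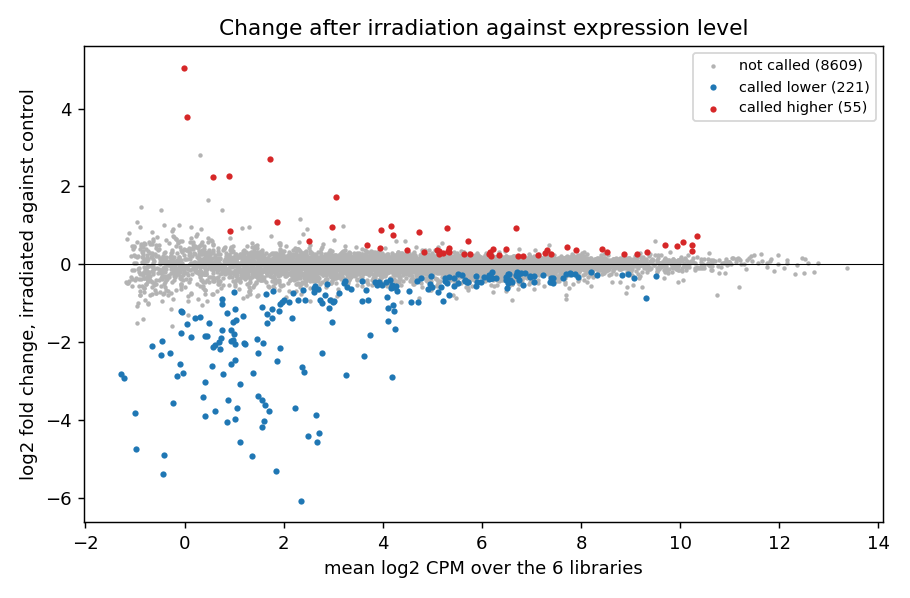
Log2 fold change of irradiated against control libraries (vertical) against mean log2 CPM over the 6 libraries (horizontal) for 8885 genes, each point 1 gene. The 221 genes called lower (blue) outnumber the 55 called higher (red), and most of the large changes lie at low expression.

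The 4 stem-cell genes fixed in advance all fell. The argonaute gene ago2-1 (Smp_179320), whose protein binds small RNAs, had 32.0, 32.8 and 32.7 CPM in controls A, B and C and 4.12, 5.09 and 4.01 in irradiated A, B and C, a log2 fold change of -2.89 (SE 0.09, adjusted p = 3.50e-07, edgeR). nanos-2 (Smp_051920), a post-transcriptional regulator of germ and stem cells, fell from 20.2, 22.8 and 19.2 CPM to 2.16, 6.06 and 4.35, a log2 fold change of -2.35 (SE 0.26). The fibroblast growth factor receptor fgfrA (Smp_175590) fell from 30.6, 28.6 and 27.2 CPM to 8.08, 9.72 and 9.61, a log2 fold change of -1.66 (SE 0.09). Its relative fgfrB (Smp_157300) fell less, from 33.2, 29.2 and 31.5 CPM to 15.2, 17.0 and 15.8, a log2 fold change of -0.97 (SE 0.08). In the list of germline and stem cell RNA regulators and FGF receptors, 5 of 9 measured members were lower and none higher (7 lower when adjusted over the list alone), with a median log2 fold change of -0.52 (camera adjusted p = 3.22e-30, and adjusted p = 0.02697 with an estimated correlation). The 4 fixed genes are 4 of the 5 members called lower. Since the study took these genes from such worms, their direction and the p-values of the list are not independent evidence.

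**Figure D2:**
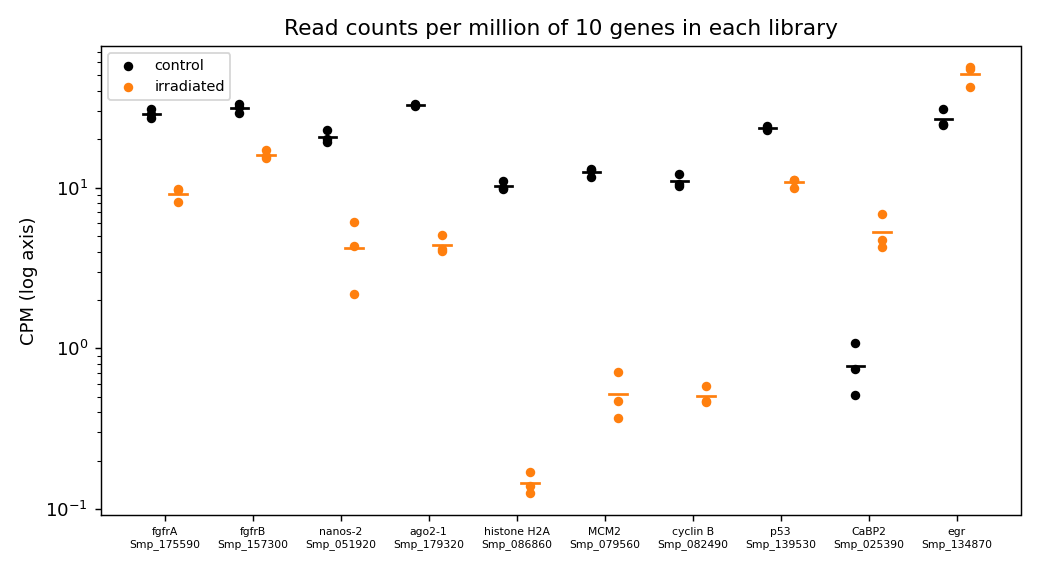
CPM on a log axis of 10 genes in each of the 6 libraries, control in black and irradiated in orange, with a bar at each group mean (n = 3). The stem-cell and division genes lie lower in every irradiated library, from 10.2 to 0.144 CPM on average for histone H2A, while CaBP2 and egr lie higher.

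Among genes with a product name and a mean log2 CPM of at least 1, the largest falls were led by a histone gene and genes of cell division. A histone H2A gene (Smp_086860) went from 10.2 ± 0.687 to 0.144 ± 0.0223 CPM (SD, n = 3), 67.5-fold lower. A rac GTPase activating protein (Smp_021590) and the cytokinesis regulator PRC1 (Smp_016870), which act when a cell splits, were 39.8-fold and 30.3-fold lower. The histone H2A, rac GTPase activating protein and PRC1 genes had 3 to 5 reads in each irradiated library. Such levels lie near the limit that a count of 0 allows, so the sizes of these folds are imprecise. A protein with ankyrin repeats named for uveal autoantigen (Smp_129710) was 20.3-fold lower, the cohesion factor eco1 (Smp_065150) 16.3-fold, the spindle motor kinesin eg-5 (Smp_149260) 15.7-fold and a myosin V gene (Smp_176000) 13.02-fold. Adjusted p for these ranged from 3.50e-07 to 1.45e-05 (edgeR). Above that level the same H2A and rac GTPase activating protein genes fell the most whatever the product name. Below it the kinase Smp_158950, named after its values were seen, was 42.3-fold lower. This kinase had 91 exonic reads in the controls and 2 after irradiation, so its fold is imprecise too. The called falls with the highest mean CPM over both groups were the gut peptidase Smp_002600, at 804 ± 39.4 in controls and 657 ± 42.3 after irradiation, and the hypothetical protein Smp_154010, at 825 ± 244 and 454 ± 77.0. The call of the latter was lost without control B, control C, irradiated A or irradiated C, with adjusted p between 0.1 and 0.2 in each.

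The DNA replication list fell as a group. Of 44 measured members, 17 were lower and none higher, and the count adjusted over the list alone was also 17 (camera adjusted p = 3.22e-30, and adjusted p = 0.002773 with an estimated correlation). The MCM genes encode the helicase that opens DNA for copying. MCM2 (Smp_079560) went from 12.5 ± 0.727 to 0.518 ± 0.174 CPM, MCM4 (Smp_172530) from 12.02 ± 0.325 to 0.811 ± 0.161, MCM5 (Smp_143490) from 17.2 ± 1.14 to 2.37 ± 0.0828 and MCM6 (Smp_094140) from 25.3 ± 0.537 to 9.12 ± 0.950. These are log2 fold changes of -4.57, -3.88, -2.85 and -1.47, each with an SE under 0.2. A second gene also named MCM2 (Smp_054840) fell less, with a log2 fold change of -0.68. A Fisher's exact test set 17 of 44 members called lower against the other tested genes (odds ratio 26.6, adjusted p = 1.97e-15 over 18 lists). The same test passed for the stem cell regulators (adjusted p = 9.51e-06), mitosis (4.41e-05) and DNA repair (0.0011) and for no other list, with 0.2116 for the histones. The pass of the stem cell regulators is not independent evidence, since 4 of their 5 called members were fixed from knowledge of this study's own work. The median of the list was only -0.14, since 27 members were not called.

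In the list of mitosis and cell cycle genes, 8 of 42 measured members were lower and none higher (11 lower and 1 higher when adjusted over the list alone). The name pattern of the list missed division genes that fell, among them PRC1, kinesin eg-5 and eco1 above. It also took an ATP:guanidino kinase, so 8 of 42 is not the share of all division genes that fell. Cyclin B (Smp_082490) fell with a log2 fold change of -4.42 (SE 0.16), cyclin B3 (Smp_047620) with -2.79 (SE 0.17) and the spindle checkpoint gene mad2 (Smp_056350) with -2.19 (SE 0.20). The cdc45-related gene (Smp_047610), whose protein works in replication, fell with -2.63 (SE 0.22). The list was lower with camera (adjusted p = 2.65e-05, and adjusted p = 0.02697 with an estimated correlation), though its median was -0.03 and 17 members lay above 0. Of 28 core and linker histone genes in the file, 16 were tested. The others had at most 53 reads over the 6 libraries, so their change is not known. Among the 16, 2 were lower and none higher: the H2A gene above and a second (Smp_002930), at 1.248 ± 0.200 and 0.527 ± 0.0576 CPM. The call of the second was lost without control B, control C, irradiated A or irradiated C, where its adjusted p was between 0.1 and 0.15, and with DESeq2 (adjusted p = 0.07399). The list was called lower (adjusted p = 0.001889), a call lost with an estimated correlation (adjusted p = 0.2872) and without irradiated B (adjusted p = 0.05539), and its median was -0.05. Histone genes are near-identical copies and can share reads. In uniquely mapped exon reads alone, the log2 ratios of the 2 called genes were -6.05 and -1.18, the same as in total exon reads. Shared reads are thus argued against as the cause of these 2 falls.

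Of 51 measured genes of DNA damage and repair, 7 were lower and none higher (12 lower and 1 higher when adjusted over the list alone, camera adjusted p = 2.57e-05, and adjusted p = 0.02697 with an estimated correlation). The other 44 were not called, and the median was -0.08 with 16 members above 0. The p53 gene (Smp_139530), a guardian of the damage response in animals, went from 23.5 ± 0.703 to 10.7 ± 0.647 CPM. The recombination genes named rad54 (Smp_194820 and Smp_026030) fell with log2 fold changes of -4.06 and -2.01, and rad50 (Smp_135900) with -2.29. In the apoptosis list, 0 of 13 members passed in either direction in edgeR, nor when adjusted over the list alone, with a median log2 fold change of 0.06 (camera adjusted p = 0.4312). At an unadjusted p under 0.05 there were 3, and DESeq2 called 0. Its most abundant members, an inhibitor of apoptosis protein (Smp_076370) and a bax inhibitor (Smp_044000), had log2 fold changes of -0.02 (SE 0.06) and 0.09 (SE 0.05).

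Some signalling and transcription factor genes changed without their lists. Among 41 genes of developmental signalling, 2 were lower and 2 higher (10 and 5 adjusted over the list alone, camera adjusted p = 0.5385). The receptor gene notch (Smp_105360) fell from 10.3 ± 0.518 to 4.76 ± 0.944 CPM, and Smad1, of the transforming growth factor pathway, from 82.5 ± 5.69 to 64.8 ± 5.56. Noggin (Smp_099440) and a second smad (Smp_169780) were higher by 0.25 and 0.34 on the log2 scale. The calls of Smad1, noggin and this smad were lost in most fits that left out a library. The name pattern of the list missed a type I receptor of transforming growth factor-beta (Smp_067260), named after its values were seen. That receptor gene was called lower, with a log2 fold change of -2.05 (adjusted p = 0.007671, edgeR). Of 53 homeobox, Sox, forkhead and nuclear receptor genes, 1 was lower and none higher (5 lower adjusted over the list alone). It was a sox gene (Smp_076600), 4.37-fold lower. The name pattern missed the hormone receptor gene dHR4 (Smp_041540), which was among the genes lower by at least 2-fold. It had 322 exonic reads in the controls and 88 after irradiation, and was named after its values were seen. The list had an adjusted p of 0.08151, and it passed without control A (adjusted p = 0.0499) and without irradiated B (adjusted p = 0.01164). Its abundant members Smp_105090 and Smp_199560 had log2 fold changes of -0.25 (SE 0.08, adjusted p = 0.1056, edgeR) and 0.00 (SE 0.05). The former was called lower by DESeq2 (adjusted p = 0.03064), without irradiated B (0.01161) and with the replicate letter as a block (0.005655).

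Few genes in the lists of differentiated tissues were called. In the tegument and surface list, the syncytial skin of the worm, 3 of 61 measured members were higher and none lower (7 higher adjusted over the list alone). These were the surface antigen Sm29 (Smp_072190), from 577 ± 42.9 to 718 ± 27.9 CPM, a tetraspanin (Smp_181530), from 64.0 ± 7.45 to 84.1 ± 4.20, and an annexin (Smp_074140), from 688 ± 53.6 to 962 ± 158. Each call was lost without control B, control C, irradiated A or irradiated C. The list rose with camera (adjusted p = 0.000662) but not with an estimated correlation (adjusted p = 0.3542). Of 36 muscle genes, 2 were lower and none higher (6 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.2864, but lower with fry at an adjusted p of 0.03874). The median log2 fold change of the muscle list was only -0.01, and 16 members lay above 0. The gene named paramyosin (Smp_169970) fell 11.3-fold, from 5.44 ± 0.534 CPM, and titin (Smp_163920) from 123.4 ± 5.78 to 92.8 ± 7.41, a call lost without control C (adjusted p = 0.0559). Of 53 neuron genes, synapsin (Smp_126990) was lower and a synaptotagmin (Smp_069120) higher, with log2 fold changes of -0.21 and 0.33 (2 and 2 adjusted over the list alone, camera adjusted p = 0.1169, but higher with fry at an adjusted p of 0.03199), and both calls were lost without control B, control C, irradiated A or irradiated C. Of 15 gut protease genes, only the peptidase Smp_002600 above was lower and none higher (2 lower adjusted over the list alone, camera adjusted p = 0.1169, and 0.01913 without control B). Its call was kept only without irradiated B among these fits. The asparaginyl endopeptidase Sm32 had 5539 ± 310 and 4675 ± 293 CPM (adjusted p = 0.07639, edgeR). It was called lower by DESeq2 (adjusted p = 0.003941), on exon-exon reads (0.04927), without irradiated B (0.01798) and with the replicate letter as a block (0.03516). The saposin gene Smp_000260 had 4030 ± 222 and 4053 ± 129 CPM.

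**Figure D3:**
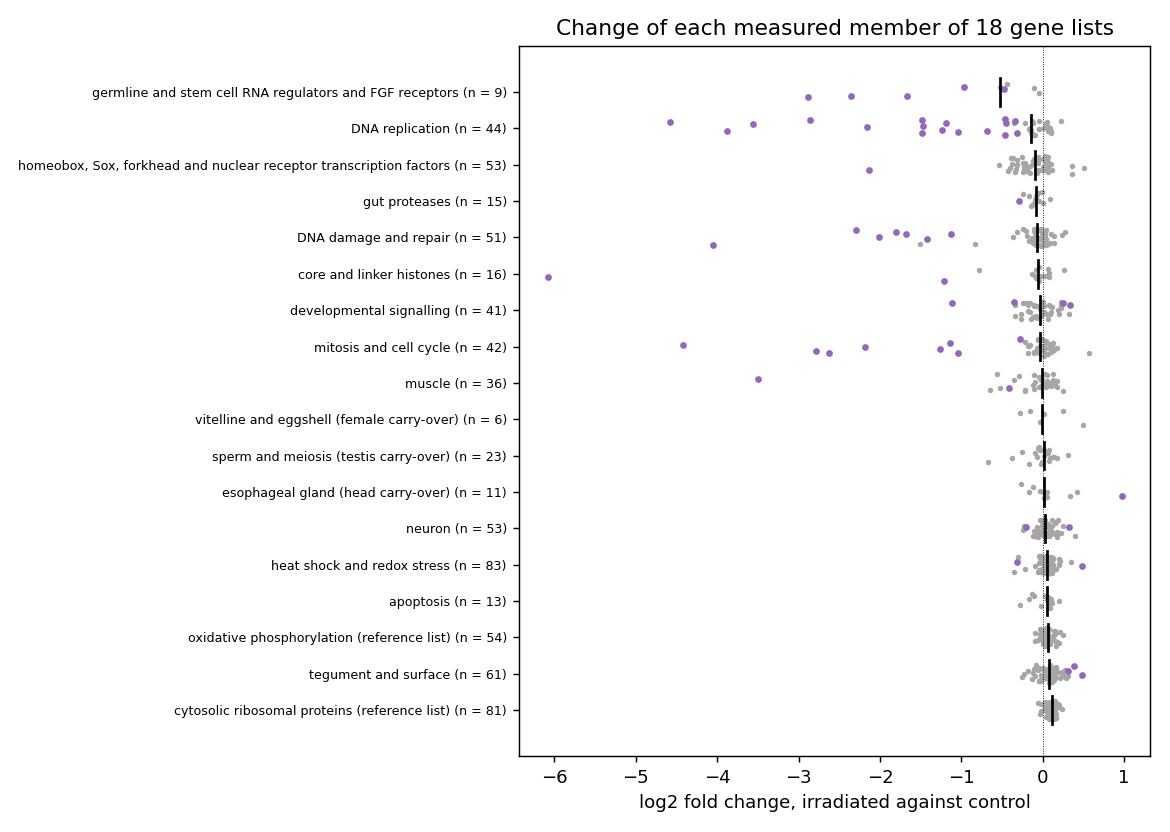
Log2 fold change, irradiated against control, of each measured member of the 18 lists, 1 point per gene, with called genes in purple and a black bar at the list median. Large falls stand in the lists of replication, mitosis, DNA repair and stem-cell regulators, with 1 each in the histone (Smp_086860), muscle (paramyosin) and transcription factor (sox) lists.

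Lists for tissue that dissection should have removed, or that a male lacks, were not called as groups with camera. Of 23 sperm and meiosis genes, 0 were called in either direction in edgeR or adjusted over the list alone, with a median log2 fold change of 0.01 (camera adjusted p = 0.8047), while 2 had an unadjusted p under 0.05 and DESeq2 called 0. The most abundant were the histone chaperone NASP (Smp_058320), at -0.17 (SE 0.05), and mre11 (Smp_068110), at -0.02 (SE 0.06), both of which dividing or somatic cells use too. NASP was called lower with the replicate letter as a block (adjusted p = 0.03267, edgeR). Of 6 vitelline and eggshell genes 0 were called by edgeR, adjusted over the list alone or by DESeq2, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.9168), and the major egg antigens Smp_049250 and Smp_049300 had log2 fold changes of -0.03 and -0.15. In the esophageal gland list, chosen to mark the head, 1 of 11 was higher and none lower (2 higher adjusted over the list alone, camera adjusted p = 0.1169, but fry called it higher at an adjusted p of 0.01692): the venom allergen-like gene SmVAL8, from 11.9 ± 1.95 to 23.5 ± 1.36 CPM. MEG-6 (Smp_163710) and SmVAL6 had log2 fold changes of 0.02 and -0.12. In controls MEG-6 and SmVAL6 had 1146 ± 41.3 and 872 ± 66.4 CPM although heads were cut away. The egg antigen Smp_049250 had 719 ± 25.1 CPM in these male worms. At such levels these genes may not mark the absent tissue, so their change does not gauge carry-over. Members with too few reads to test included a MEG-4 gene (Smp_085840) and an eggshell precursor gene (Smp_000430). They had 5 and 26 reads over the 6 libraries.

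Stress and housekeeping lists moved by small amounts. Of 83 heat shock and redox genes, 1 was higher and 1 lower, both over all genes and adjusted over the list alone. A heat shock protein (Smp_049270) rose from 1003 ± 62.7 to 1405 ± 115 CPM, and a DNAj-like gene (Smp_068230) was lower with a log2 fold change of -0.31, a call lost without control B, control C, irradiated A or irradiated C. None of 81 ribosomal protein genes and none of 54 oxidative phosphorylation genes was called in edgeR or adjusted over the list alone, with medians of 0.11 and 0.06. At an unadjusted p under 0.05 there were 15 and 10, and DESeq2 called 1 in each. The 3 lists were higher with camera (adjusted p = 0.003752, 5.42e-07 and 0.001889) and none with an estimated correlation (adjusted p = 0.5123 in each). The oxidative phosphorylation list was not called without control B (adjusted p = 0.05664). The L40 genes Smp_009580 and Smp_046690 had log2 fold changes of -0.02 and 0.03, and the mitochondrial genes cox1 and nad4 0.04 and 0.07.

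Rises were few and mostly small. The calcium-binding protein CaBP2 (Smp_025390) rose the most among named products, from 0.780 ± 0.286 to 5.28 ± 1.39 CPM, a log2 fold change of 2.71 (SE 0.28, adjusted p = 0.0004917, edgeR). The scarcer genes Smp_121230 and Smp_136890, without a product name and named after their values were seen, rose more: Smp_121230 from 0.104 ± 0.113 to 1.68 ± 0.476 CPM, a log2 fold change of 3.77 (SE 0.52, adjusted p = 0.003126), and Smp_136890 from 0.0505 ± 0.0582 to 1.58 ± 1.19 CPM (adjusted p = 0.02087), with at most 2 reads in any control. The hypothetical protein Smp_132830 went from 3.77 ± 0.160 to 12.5 ± 2.001 CPM. The early growth response gene (Smp_134870), which encodes an immediate early transcription factor, went from 26.7 ± 3.58 to 50.9 ± 7.77 CPM, and Smp_010370, named for a polyposis locus protein, from 70.4 ± 9.91 to 135 ± 20.1. Adenosine deaminase (Smp_035700) was 1.79-fold higher. A further adhesion receptor (Smp_058380) was 1.70-fold higher and hypoxanthine-guanine phosphoribosyltransferase (Smp_049850), a purine salvage enzyme, 1.51-fold. Both calls were lost without control A, control C or irradiated A, that of the receptor also without control B and that of the enzyme also without irradiated C. The most abundant called rises were the actin-severing protein gelsolin (Smp_008660), from 972 ± 122 to 1605 ± 342 CPM, and the unnamed gene Smp_202970, from 1069 ± 71.3 to 1356 ± 109. The gelsolin call was lost without control B or control C, and that of Smp_202970 without control B, control C, irradiated A or irradiated C.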

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

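All tests in this part were chosen after the main results were seen. Those on thinned libraries and on intronic change against other genes were set out before their own outcome was seen, and the tests of testis tissue, of unique intronic reads and of splits after it.

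Intronic reads, the gene reads outside exons, are not used in the comparisons of the report. Among 7528 genes with enough of them, 12 were called lower and 5 higher after irradiation (edgeR quasi-likelihood test). Among the falls, that of the kinase Smp_009600, named after its values were seen, rested on shared reads. Its intronic log2 fold change went from -0.91 to -0.16 with uniquely mapped reads alone, while the other falls changed little. The 5 were CaBP2 (Smp_025390), Smp_010370, Smp_139140, Smp_121230 and the fatty acid elongation gene Smp_130370, named here after their values were seen. The last had an intronic log2 fold change of 0.97 and an exonic one of 1.16, which missed the threshold (adjusted p = 0.05514).

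Among the 100 genes lower by at least 2-fold, 78 had at least 20 intronic reads in the controls, and in 72 of these the intronic reads fell less than the exonic ones. The median log2 ratio was -0.83 for intronic and -2.09 for exonic reads. The rac GTPase activating protein (Smp_021590) had 477 exonic reads in the controls and 13 after irradiation, but 191 and 179 intronic ones. Reads shared with repeats or paralogs are argued against as the cause, because uniquely mapped reads alone gave a median of -0.81. An intronic background untouched by irradiation is argued against as the whole signal, because the fitted median of 69 of these genes was -0.79 while that of 7314 genes not called was -0.19. A mixture of such a background with unspliced RNA of the lost transcripts may remain, and other transcripts within the introns were not tested.

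Part of the genes of dividing cells were called lower, 17 of 44 in the replication list and 8 of 42 in the mitosis list. The name pattern of the latter missed some division genes that fell. A difference in depth is argued against, because 93 of the 100 genes lower by at least 2-fold were still called lower with every library thinned to the smallest. Testis tissue left in the control pools could lower the same genes. The sperm and meiosis list had a median log2 fold change of 0.013 against -1.24 for the 17 replication genes called lower, but some of its genes are also used in somatic cells, and nanos (Smp_055740) and boule (Smp_144860), genes of the germline, had few reads. In controls A, B and C nanos had 15, 11 and 6 and boule 1, 5 and 1, and in irradiated A, B and C nanos had 7, 2 and 4 and boule 1, 2 and 1. The tektin gene Smp_162540 of the sperm list had 0, 0 and 1 reads in the controls and 2, 0 and 3 after irradiation. Nanos runs the way such tissue would make it run, boule differs only in B, and tektin runs the other way, but these counts are too low to test, so this stays open. Loss of stem cells and a lower level of these transcripts in cells that remained cannot be told apart in bulk tissue and were not tested.

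Of the 10 ways to split the 6 libraries into 3 and 3, the real one (1 of 10) gave 221 genes lower and 55 higher, and the highest of the others gave 0. By at least 2-fold the real split gave 100 and 7 and the highest of the others 0. Every other split put libraries of both groups on each side, where a real difference would itself widen the spread. The 0 calls there thus do not show what chance alone would give. A design of this size has too few splits for a share under 0.05.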

How the results depend on the processing

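Gene reads with introns, exon-exon reads, thinning and the tegument pattern as written were chosen after seeing the data. Of 50 called named genes, 33 stayed past the threshold in every setting that gave them a value, and 0 of 1164 named-gene values reversed (121 lost a call and 8 gained one). The counts of genes lower, higher, lower by 2-fold and higher by 2-fold (221, 55, 100 and 7) moved as follows; the cause was not tested except where fewer genes or libraries entered. DESeq2 gave 480, 125 and 11 for lower, higher and higher by 2-fold. At least 5 CPM in 3 libraries, with fewer genes, gave 77, 26, 27 and 1. limma on log2(RPKM + 0.5) gave 140 lower and 63 lower by 2-fold, and with a pseudocount of 0.1 139 lower. Exon-exon reads gave 4 higher by 2-fold. Leaving out 1 library gave 119 to 723 lower, 16 to 129 higher and 3 to 14 higher by 2-fold. With the replicate letter as a block 851, 277 and 12 were lower, higher and higher by 2-fold. The block kept all 276 calls of the main fit. The deviations of same-letter libraries from their group means correlated at 0.04, 0.18 and -0.10, and not every library correlated best with its own letter. With 3 libraries per group, these values cannot show whether the letters pair the libraries.

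With an estimated correlation the calls were lost for histones (adjusted p = 0.2872), ribosomal proteins, heat shock and oxidative phosphorylation (0.5123) and tegument (0.3542). fry, which asks if a list moves one way, gave 0.1904 for ribosomal proteins, 0.1276 for heat shock, 0.1545 for oxidative phosphorylation, 0.0605 for tegument, 0.01692 for the esophageal gland, 0.03874 for muscle and 0.03199 for neurons. The block gave 0.0396 for the transcription factors. Over fits that left out a library, adjusted p ran from 0.01164 to 0.2736 for the transcription factors, 0.01913 to 0.3129 for gut proteases, 0.0002937 to 0.05664 for oxidative phosphorylation and 0.0003593 to 0.05539 for histones. Of the 100 genes lower by at least 2-fold, 27 were still called lower with at least 5 CPM in 3 libraries, 66 on exon-exon reads, which also kept 146 of all 276 calls, and 93 with every library thinned to the smallest.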

Other observations

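The tests of GO terms were chosen after seeing the data, and that of neighbours was written before its result was seen. Among terms in the deposited table, 13 were enriched among genes called lower and 2 among genes called higher, of 625 tested in each direction. Cell cycle led the former, with 35 called of 171 genes against 4.33 expected (adjusted p = 1.33e-19), and 11 of 14 genes of DNA replication initiation were called lower (adjusted p = 4.41e-13). The terms among genes called higher were extracellular region, with 10 called of 233 genes against 1.41 expected (adjusted p = 0.0001197), and cell differentiation, with 4 of 53 (adjusted p = 0.02498). As many genes of the latter term, 4 of 53, were called lower, against 1.34 expected (adjusted p = 0.9289). The first group held a macroglobulin (Smp_089670), from 827 to 1141 CPM, a serine peptidase (Smp_002150), from 862 to 1276 CPM, the gynecophoral canal protein GCP, from 421 to 507 CPM, and a laminin gamma chain (Smp_163810), at a log2 fold change of 0.31. The rises of the second held Jagged (Smp_141250), a ligand of notch, from 0.552 ± 0.338 to 2.83 ± 1.01 CPM (SD, n = 3), while the receptor notch was lower. These genes were named after their values were seen.

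Genes called lower lay next to each other more often than random sets. Neighbours here are genes consecutive among the 7877 tested ones matched to the assembly. No limit was set on distance, so genes without a test can lie between them. Of 202 called genes matched to the assembly, 11 neighbouring pairs were formed, against a median of 5 and an upper limit of 10 (of the middle 95% of draws) in 10000 random sets of the same size, 1.28% of which had as many pairs. The margin is small. Chance placement is argued against only weakly by these 11 pairs, and one candidate explanation is a gene split into 2 models. Within pairs the median absolute difference of log2 fold change was 0.59, between the 2.5th percentile (0.30) and the median (0.94) of random pairs, so this stays open. Whether neighbours overlap on opposite strands, where reads cannot be told apart here, was not tested. One pair was cyclin B3 (Smp_047620) and the cdc45-related gene (Smp_047610), and another held MCM2 (Smp_079560) beside a second gene also named MCM2 (Smp_054840), at -4.57 and -0.68.

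Among 22 features without exons, mostly rRNA, 0 were called in edgeR and 0 had an unadjusted p under 0.05.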
